A study of Mus musculus with 8 samples.

How the data were processed

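Hematopoietic stem cells were isolated from the bone marrow of C57BL/6 mice of 2 genotypes, 4 control mice with floxed Atg12 alleles, and 4 conditional knockout mice that also carried Mx1-Cre, a recombinase gene switched on by interferon. Per the series' design, all mice were injected with poly(I:C), a synthetic double-stranded RNA that induces interferon, at 4 weeks of age, and cells were taken from individual mice 2 to 3 months later, at an age given in the labels as 3 to 4 months. Per the labels, the cells were sorted in 2 rounds for absence of lineage markers, Flk2 and CD48 and presence of c-Kit, Sca-1 and CD150. RNA was isolated with the PicoPure kit, amplified with the Ovation Pico WTA system and hybridised to Affymetrix Gene ST arrays, per the labels' protocols and the series' design. Whole-transcriptome amplification of RNA from few cells can enlarge the spread of weakly expressed genes between arrays.

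The deposited values were log2 signals, 1 value per transcript cluster (a set of probes spread over a gene) and array. RMA and limma are named in the submitters' processing notes, without versions or settings; RMA subtracts background, applies quantile normalization between arrays and summarises probes. The annotation and genome build behind the gene symbols were not given in the sources used here. The deposited table with gene names and the deposited table of series values held the same 28853 features, and the largest difference between them was 0. Columns were matched to samples by name, and 0 columns were left unmatched. RMA equalises the distribution of signal between arrays, so a change that shifted most genes the same way would not be seen.

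Of the 28853 features, 1494 carried no gene symbol and were left out of the tests. Among the remaining 27359 features, 1502 symbols had more than 1 feature (4648 features together), and the feature with the highest mean over the 8 arrays was kept, giving 24213 genes. Of these symbols, 21687 matched a current RefSeq mouse symbol, 1138 matched only a synonym and 1388 matched neither, and the symbols are printed as the file gives them. Arrays hold no read depth, and their number, 4 per group, limits the precision.

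Knockout was compared with control in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the log2 values, without filtering on signal and without covariates. P-values were adjusted by the Benjamini-Hochberg method, and a gene was counted as changed at an adjusted p under 0.05. Single genes and list means were also compared by a two-sided exact permutation test over the 70 assignments of 8 arrays, whose smallest possible p is 0.0286. Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with adjustment over 28 lists. The lists hold 703 genes, of which 696 were measured and 7 (Eno1, Ahsp, Hba-a1, Gp6, Isg15, Rps3a and Rps27) were not found under their symbols. The lists cover autophagy, lysosome, energy metabolism, stress responses, stem cell identity and ageing, blood lineages, other cell types the sort could hold, cell cycle, interferon and inflammatory genes, p53 targets, ribosomal proteins and DNA methylation. The list shift is the difference between the group means of the list's average per array, with the SE of that difference over arrays.

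The lists, the tests, the rule for named genes and the alternatives named first below were fixed before the data were examined. Genes named were Atg12, the 10 genes per direction that ranked first by p among those whose groups did not overlap (places not filled by genes past the threshold were given as values), the 2 members of smallest p in each list, and the genes of the sort markers. Predicted gene models, receptor families and small RNAs were counted and not named. Outside this rule, Gata2 and Mcpt8 were named after their values were seen, since they passed when adjusted over their list alone. Other genes named outside it, besides sex-linked genes and the neighbours of Atg12, are marked in the text as chosen after their values were seen.

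Alternatives comprised the replicate number as a block, omission of each array in turn, other ways to choose features, a signal filter, repeated quantile normalization, median centring, the series values, limma-trend, robust eBayes, array weights, Y-linked signal as a covariate, other thresholds, and 3 other list tests. Xist signal as a covariate, omission of knockouts 3 and 4 together, and a filter at the level of transcripts that should be absent were added after seeing the data. The fit was tested on simulated data with the means and spreads of the 24213 genes for knockout minus control. It recovered 24 of 67 genes changed by 0.5 on the log2 scale, 65 of 67 changed by 1 and 66 of 66 changed by 2, and called 8 unchanged genes. All of these genes were changed in the same simulated set, which eases the adjustment, whereas 1 gene passed in the real data. The noise was normal, with the spreads moderated by the fit. These rates therefore do not give the chance of finding a change in the real data. In 20 simulated sets with independent genes, camera recovered a list shifted by 0.3 in 20 sets and called 3 of 540 unshifted lists. Genes in that simulation were uncorrelated, unlike those on real arrays.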

Results

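Gene expression was measured in bone marrow cells sorted as hematopoietic stem cells (HSCs), which give rise to all blood lineages, from 4 control and 4 Atg12 conditional knockout mice. Atg12 encodes a ubiquitin-like protein that is joined to Atg5 and is needed to form autophagosomes, the vesicles that carry cell contents to the lysosome. The comparison addressed how loss of this autophagy gene alters the transcripts of HSCs, as the labels name the cells, from mice aged 3 to 4 months. Only the knockout mice carried Mx1-Cre, so an effect of Cre itself cannot be told apart from loss of Atg12. Each of the 8 arrays gave a log2 RMA signal for 24213 genes. On all 8 arrays Slamf1, the gene of the sort marker CD150, read 2.22 to 2.98. That lies within the 1.64 to 3.20 read by sex-linked transcripts on arrays that should lack them. Of 29 genes of HSC identity and quiescence, 25 had a mean above that level, and Slamf1, Mecom, Tek and Esam did not. Among all 24213 genes, 14697 had a mean above that level, as had 22 of 22 early myeloid progenitor genes. Fgd5 (3.32) and Procr (3.49) lay just above it and Kit (8.50) far above, chosen after their values were seen. These counts do not settle which cells were sorted. Mpo, a gene of myeloid progenitors also chosen after its value was seen, averaged 12.21. Levels of different probe sets are not on a common scale. HSC below names the samples as sorted. Array medians lay between 3.76 (knockout 2) and 3.92 (knockout 3), and correlations across genes between pairs of arrays lay between 0.986 and 0.993.

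Atg12 signal fell in the knockout samples, from 6.44 ± 0.08 in controls to 5.50 ± 0.13 in knockouts (SD, n = 4 arrays each; two-sided exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give). The log2 difference was -0.93 (SE 0.10), which left 0.524 of the control signal. Every knockout array, at 5.35 to 5.66, lay below every control array, at 6.37 to 6.55. Atg12 was the 1 gene of 24213 past the threshold (limma, adjusted p = 0.031), with 0 genes higher. The sources used here do not say which part of the gene was deleted or which exons the probes cover. The call was lost when any single array was left out (adjusted p 0.0542 to 0.226, log2 difference -0.98 to -0.88). With all 8 arrays it was also lost with the replicate number as a block (0.227), Y-linked (0.112) or Xist (0.162) signal as a covariate, and arrays centred on their median (0.068).

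At an unadjusted limma p under 0.05, 1195 genes differed, 589 higher and 606 lower in knockout, against 1210.65 that chance alone would give. The groups did not overlap for 703 genes, or 2.90%, where chance gives 2.86%. The second smallest adjusted p was 0.362.

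The genes that ranked first among those higher in knockout did not pass the test and are given as values. They included the interferon-induced 2'-5' oligoadenylate synthetases Oas1a (log2 difference 1.11, SE 0.17), Oas1g (1.07, SE 0.20) and Oasl2 (0.75, SE 0.16), and the interferon-induced Ifi27 (0.51, SE 0.10). Oas1a and Oas1g are close paralogs, and probes of one can bind transcripts of the other. Cdo1, encoding cysteine dioxygenase, had the largest difference among them, 2.26 (SE 0.47), with knockout arrays at 7.78 to 8.01 and control arrays spread from 4.15 to 6.77. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, differed by 0.87 (SE 0.15), and Tfrc, the transferrin receptor, by 0.74 (SE 0.15). Lrg1 differed by 1.38 and Atp11a by 0.79, and Nudt10 was not above the level of absent transcripts on any array. The adjusted p of these 10 genes lay between 0.362 for Oas1a and 0.771 for Oasl2 (limma).

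Among genes lower in knockout, the inducible Hsp70 genes Hspa1a (log2 difference -2.77, SE 0.52) and Hspa1b (-2.24, SE 0.47) had the largest differences of those named, and did not pass the test. Hspa1a control arrays ranged from 6.01 to 8.77 and knockout arrays from 4.65 to 5.76. Its difference was -1.35 among arrays with Xist alone (1 control, 2 knockout), -3.45 among arrays with Y-linked signal alone (3 control, 1 knockout) and -2.15 with Xist signal as a covariate. The only knockout with Y-linked signal alone was knockout 3, which lay apart from the other arrays on the first principal component (-39.5). Without control 4, Cybb, Oas1g and Hspa1a passed the threshold (limma adjusted p 0.0369, 0.0369 and 0.0328). Control 4 was the only control with Xist signal, and for each of these genes it was the control nearest to the knockouts. Without it, sex and genotype are harder to tell apart. Hspa1a and Hspa1b are nearly identical in sequence and count as 1 signal here. Alox5, encoding 5-lipoxygenase, differed by -0.60, the transcriptional cofactor gene Eya1 by -0.69, Bpifc by -0.95, Gnb4 by -0.71 (3 of 4 knockout arrays above the level of absent transcripts) and Lpcat2 by -0.64, and Cyp21a1 was not above the level of absent transcripts on any array. Tmem71 was at 4.58 in controls and 3.58 in knockouts. Their adjusted p lay between 0.651 for Hspa1a and 0.803 for Lpcat2 (limma).

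**Figure D1:**
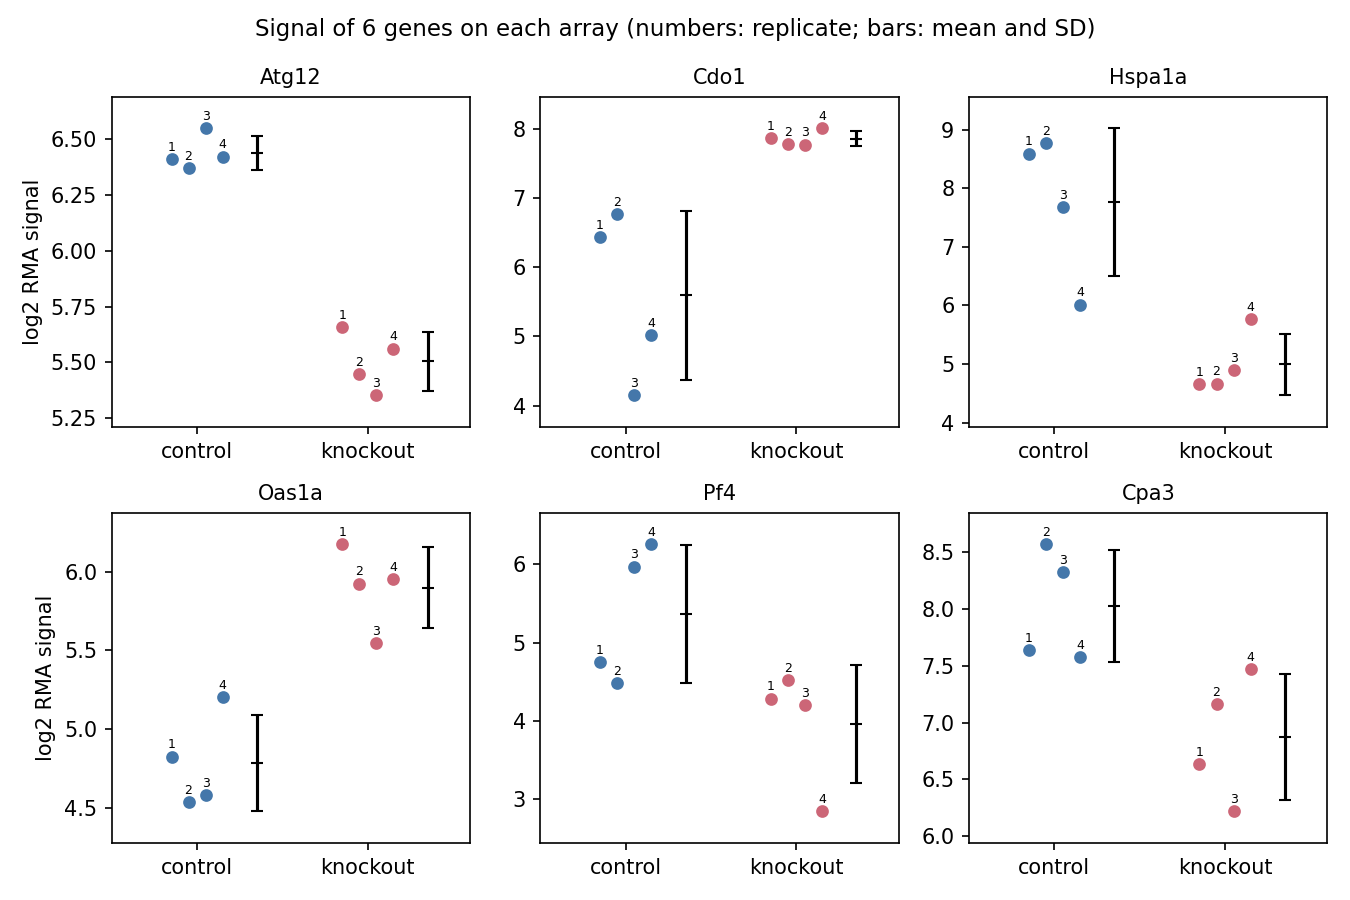
Log2 RMA signal (vertical axis) of 6 genes on the 4 control and 4 knockout arrays; points are arrays numbered by replicate, and bars give the group mean and SD. Atg12 knockout arrays lie at 5.35 to 5.66, below all control arrays, while Cdo1, Hspa1a and Pf4 vary widely within a group; only Atg12 passed the test across all genes.

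Interferon-stimulated genes rose as a list in the knockout samples by camera at the preset correlation. The mean of the 31 measured genes was 0.32 higher on the log2 scale (SE 0.11; camera adjusted p = 4.00e-12), and 28 of 31 members had a difference above 0. The call was lost with an estimated correlation (adjusted p = 0.301 with an estimated correlation). The groups overlapped in the list mean, with control 4 (4.92) above knockout 3 (4.82), and the two-sided exact permutation p was 0.0571. No member passed the test over all genes, and 2 passed when adjusted over the list alone, Oas1a and Oasl2. Members did not move alike. Ifi27l2a differed by 0.67 and Irf9 by 0.50, whereas Ifit2 was at 0.03 and Stat2 at -0.15. Of the 31 members, 27 had a mean above the level of absent transcripts. Rsad2 (mean 3.14) and, in controls, Ifi44 (mean 3.05) did not exceed it, and no difference is given for them. The genes in this comparison of members were chosen after their values were seen. Sex-linked transcripts differed between the groups' arrays. Xist was high on control 4 and on knockouts 1, 2 and 4, and Y-linked genes were high on controls 1, 2 and 3 and on knockouts 3 and 4. The list's difference was 0.22 among arrays with Y-linked signal alone (3 control, 1 knockout), 0.11 among arrays with Xist alone (1 control, 2 knockout), and 0.19 with Xist signal as a covariate. The first value rests on the outlying knockout 3 as its only knockout, and the second on control 4 as its only control.

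Genes of megakaryocytes and platelets fell as a list. The mean of the 20 measured genes was lower by -0.25 (SE 0.06; camera adjusted p = 7.81e-05; adjusted p = 0.094 with an estimated correlation), and 14 of 20 members had a difference below 0. No member passed, over all genes or adjusted over the list alone. Pf4, encoding platelet factor 4, had a difference of -1.40 (SE 0.44, with 3 of 4 knockout arrays above the level of absent transcripts), and P2rx1, a platelet ATP receptor, one of -0.65 (SE 0.17). The list mean was lower on all 4 knockout arrays than on any control array (two-sided exact permutation p = 0.0286, adjusted over 28 lists 0.4).

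Genes of mast cells and basophils also fell as a list, by -0.31 over 11 genes (SE 0.08; camera adjusted p = 0.00207; adjusted p = 0.115 with an estimated correlation). Of the 11 members, 9 had a difference below 0. No member passed over all genes, and 3 passed when adjusted over the list alone. These were Cpa3, encoding mast cell carboxypeptidase (-1.16, SE 0.29), Ms4a2, a chain of the high-affinity IgE receptor (-0.73, SE 0.23, with 2 of 4 knockout arrays above the level of absent transcripts), and the basophil protease gene Mcpt8 (-0.38, SE 0.12). Of the 11 members, 7 had a mean above the level of absent transcripts, and the list's shift was -0.50 over genes above that level and over genes at or above the median signal. With knockouts 3 and 4 left out together, the list's adjusted p was 0.0505. The groups overlapped in the list mean, with knockout 2 (4.51) above control 1 (4.50), and the two-sided exact permutation p was 0.0571.

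Only camera at the preset correlation of 0.01 made the 3 calls. The estimated correlation was 0.275 for the interferon-stimulated list. It was 0.006 for the megakaryocyte and platelet list and -0.032 for the mast cell and basophil list. Both of these are below the preset value, so a higher correlation did not cost these 2 lists the call. None of the 28 lists was called with an estimated correlation, by fry or by the exact permutation test, whose smallest p cannot pass the adjustment over 28 lists unless many lists reach it. Among the 35 ways to divide the 8 arrays into groups of 4, 20 called 3 or more lists by the same test, the real division included.

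**Figure D2:**
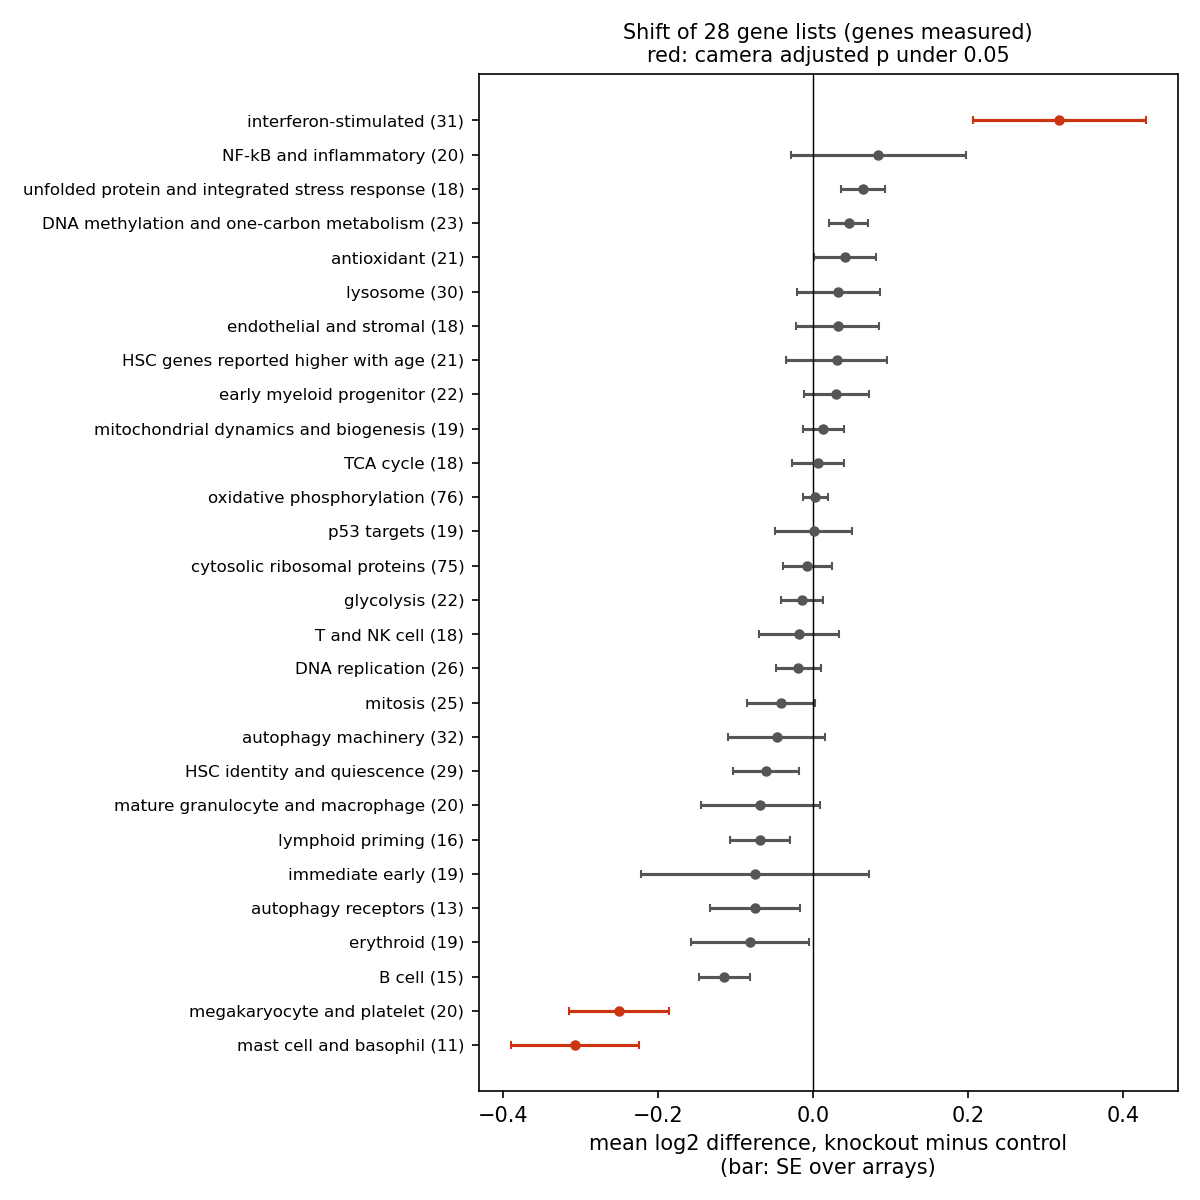
Mean log2 difference, knockout minus control (horizontal axis), of the 28 gene lists, with the number of genes measured; points are list means, bars the SE over arrays, and red marks lists called by camera at the preset correlation. The interferon-stimulated list lies at 0.32, the megakaryocyte and platelet list at -0.25 and the mast cell and basophil list at -0.31; the others lie between -0.11 and 0.08.

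Autophagy and lysosome lists were not called with all arrays and no covariate. The autophagy machinery list without Atg12 differed by -0.05 (SE 0.06, 32 genes), with Ulk1, the initiating kinase, at -0.19 and Wipi1 at -0.34. Autophagy receptors differed by -0.08 (SE 0.06), with Nbr1 at -0.19. Both lists were called lower without control 1 (-0.09, camera adjusted p 0.0101, and -0.13, 0.0039) and with Xist signal as a covariate (-0.11, 0.00778, and -0.11, 0.0398). Without knockout 3, however, the autophagy machinery list was at 0.001. The lysosome list differed by 0.03 (SE 0.05), with the sialidase gene Neu1 at 0.31 and Ctsz at 0.21, and was called higher without control 4 (0.07, adjusted p 0.0381) and without knockout 3 (0.07, adjusted p 0.03). All these calls used camera at the preset correlation of 0.01. With all arrays the estimated correlation was 0.24 for autophagy machinery, 0.20 for autophagy receptors and 0.18 for the lysosome list. The calls were not repeated with estimated correlations, so their adjusted p may be too small.

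Lists of energy metabolism had small differences and were not called. Oxidative phosphorylation differed by 0.003 (SE 0.016, 76 genes), the TCA cycle by 0.007 (SE 0.033) and glycolysis by -0.014 (SE 0.027). Members of smallest p were Uqcrfs1 (0.18) and Ndufb11 (0.15) for oxidative phosphorylation, Ogdh (-0.23) for the TCA cycle, and Aldoc (-0.60, with 2 of 4 knockout arrays above the level of absent transcripts) for glycolysis. Pcx and Eno2 were above that level on 2 and 1 knockout arrays and on 0 control arrays, and no difference is given for them. Mitochondrial dynamics and biogenesis differed by 0.013 (SE 0.026), with Pink1 at -0.12. The antioxidant list differed by 0.04 (SE 0.04), with Gclm at 0.29 and Txnrd1 at 0.16. The list of unfolded protein and integrated stress response differed by 0.06 (SE 0.03), with Xbp1 at 0.28 and Creld2 at 0.24, and was called higher by limma-trend alone (adjusted p 0.0391). DNA methylation and one-carbon metabolism differed by 0.05 (SE 0.02), with Mthfd2 at 0.24.

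The list of HSC identity and quiescence differed by -0.06 (SE 0.04, 29 genes) and was not called. Its members went both ways: 3 passed when adjusted over the list alone and 0 over all genes. Cdkn1c, the cell cycle inhibitor p57, was at 0.40 (3 of 4 control arrays above the level of absent transcripts), and the transcription factor gene Gata2 and Eya1 were at -0.64 and -0.69. HSC genes reported higher with age differed by 0.03 (SE 0.07), with Selp at 0.56 and Enpp5 at -0.55. Early myeloid progenitor genes differed by 0.03 (SE 0.04), with Hp at 0.36 and Irf8 at 0.34. Lymphoid priming differed by -0.07 (SE 0.04). The erythroid list differed by -0.08 (SE 0.08), and 13 of its 19 measured members had a mean above the level of absent transcripts. Tfrc passed adjusted over the list alone, and Aqp1 was at -0.42, with 2 of 4 knockout arrays above that level.

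Markers of other cells that a sort could hold were not called beyond the lists above. Mature granulocyte and macrophage genes differed by -0.07 (SE 0.08), with Lcn2 at 0.66. B cell genes differed by -0.11 (SE 0.03), with Cd72 at -0.64. T and NK cell genes differed by -0.02 (SE 0.05), with Nkg7 at -0.17. Endothelial and stromal genes differed by 0.03 (SE 0.05), with Pdgfrb at -0.28. A mean above the level of absent transcripts was reached by 7 of 15 B cell, 7 of 18 T and NK cell and 7 of 18 endothelial and stromal members. Most members of these lists thus gave no signal above that level, and the shifts say little about other cells in the sort. The other members that ranked first by p in their lists, Stbd1, Ppargc1a, Ltf, Rag2, Ccr9, Cd79a, Klrd1, Lum and Dnmt3l, were not above the level of absent transcripts on any array, and no difference is given for them.

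Proliferation and stress lists were not called with all arrays and no covariate. Mitosis genes differed by -0.04 (SE 0.04), with Tpx2 at -0.24 and Nusap1 at -0.21; they were called lower without control 1 (-0.08, camera adjusted p 0.0129) and with Xist signal as a covariate (-0.08, 0.0316). DNA replication genes differed by -0.02 (SE 0.03), with Mcm7 at -0.18 and Ccne1 at 0.21. The NF-kB and inflammatory list differed by 0.08 (SE 0.11), and by -0.0005 without control 1 and 0.15 without control 2; the interferon-induced chemokine gene Cxcl10, at 1.29, passed adjusted over the list alone, and Bcl3 was at 0.46. Immediate early genes differed by -0.07 (SE 0.15), with Egr1 at -0.42 (-0.19 without control 2 and -0.64 without control 1) and Jund at -0.15, and were called lower without control 1 (-0.14, adjusted p 0.0213) and without control 4 (-0.14, 0.0381), while the list was at 0.013 without control 2 and at 0.006 without knockout 1. The p53 targets differed by 0.001 (SE 0.050), with Perp at -0.82 (1 of 4 knockout arrays above the level of absent transcripts) and Gadd45a at 0.21. Cytosolic ribosomal protein genes differed by -0.007 (SE 0.032, 75 genes), with Rps14 at -0.10 and Rpl13a at 0.09, and were called lower with Xist signal as a covariate (-0.04, adjusted p 0.0398). Calls of these lists without an array or with a covariate also used the preset correlation. With all arrays the estimated correlation was 0.20 for mitosis, 0.39 for immediate early and 0.31 for ribosomal protein genes. The mean, median and test of 3 uncalled lists differed in sign, namely glycolysis, T and NK cell, and endothelial and stromal. With 1 array left out, 11 of the 28 lists, all uncalled, changed sign in at least 1 case. Most uncalled lists moved by over 1.5 times in at least 1 case, such as the antioxidant list, at 0.006 without control 1. The exceptions were the lists of unfolded protein and integrated stress response, B cell, and DNA methylation and one-carbon metabolism. Among single genes given above for uncalled lists, the differences of Wipi1, Nbr1, Ctsz, Pink1, Gclm, Txnrd1, Selp, Tpx2, Nusap1, Egr1, Gadd45a, Rpl13a and Mthfd2 moved by over 1.5 times, and none of these genes passed the test.

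The genes of the sort markers did not pass the test. Kit was at 8.56 ± 0.10 in controls and 8.44 ± 0.09 in knockouts (SD, n = 4 each), Ly6a, which encodes Sca-1, at 4.01 ± 0.34 and 4.66 ± 0.35, and Slamf1, which encodes CD150, at 2.63 ± 0.28 and 2.82 ± 0.11. Cd48 was at 8.63 ± 0.06 and 8.59 ± 0.06, and Flt3, which encodes Flk2, at 5.39 ± 0.41 and 5.32 ± 0.14. Levels of different probe sets are not on a common scale, so these values do not rank the markers.

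**Figure D3:**
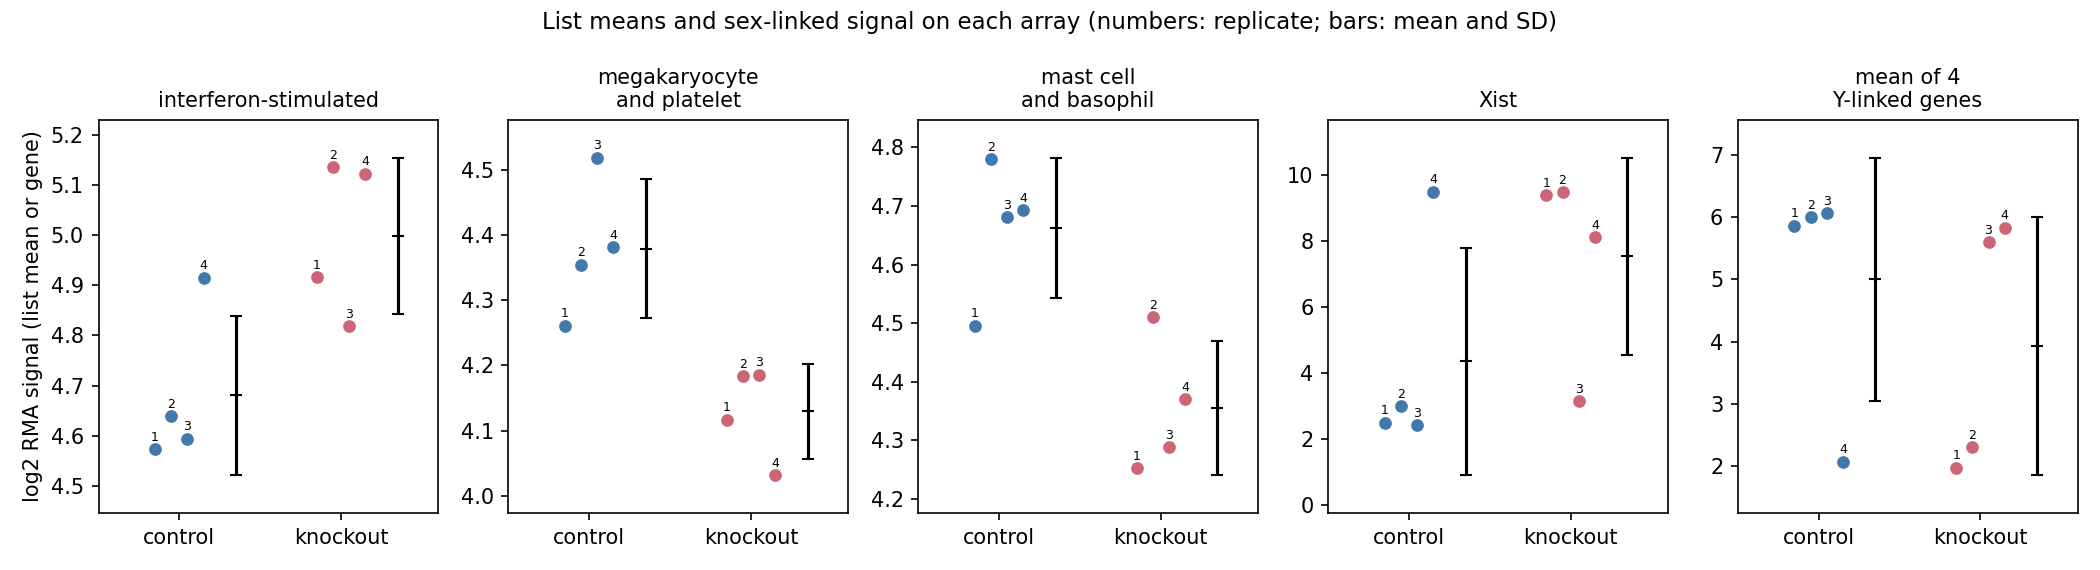
Log2 RMA signal (vertical axis) on each array: the mean of the 3 called lists, Xist, and the mean of 4 Y-linked genes; points are arrays numbered by replicate, and bars give the group mean and SD. Control 4 has Xist at 9.50 and the highest interferon-stimulated mean of the controls, and knockout 4 has both Xist, at 8.12, and Y-linked signal, at 5.83.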

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

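Both counts over divisions of the arrays in this part were planned before they were seen, and none of the tests here was chosen afterwards. In groups of 4 arrays, an array was singled out when its gap to the nearest other array took up nearly the whole range of its group. Of 222 sets of 4 values (named genes, list means and array measures), 14 were singled out, where chance gives about 1 in 20, or 11.1.

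Knockout 3 accounted for 5 of the 14. On that array the autophagy machinery list was at 5.79 (others 5.97 to 5.99), ribosomal protein genes at 11.56 (others 11.67 to 11.68), the erythroid list at 3.82 (others 3.55 to 3.56), Aqp1 at 2.76 and the upper quartile of all signals at 5.88. Control 1 accounted for 4, with Flt3 at 4.78 (others 5.56 to 5.61), Tpx2 at 6.86, autophagy receptors at 5.97 and mitosis genes at 7.69. Knockout 1 had Enpp5 at 4.13 and Egr1 at 5.08, and control 3 had Lcn2 at 7.42. Control 4 had Xist at 9.50 (others 2.42 to 3.00) and a Y-linked mean of 2.07 (others 5.86 to 6.07).

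The number of genes and lists past the threshold was compared over the 35 divisions of the 8 arrays into 4 and 4. For genes, 2 of the 35 gave as many as the real division, which called 1 gene, and the highest of the others was 1; chance was not excluded for the count. The other division set controls 1, 2 and 3 with knockout 3 against the rest, follows Xist signal and called Xist itself, whereas the real one called Atg12. For lists, 20 of the 35 gave as many as the 3 of the real division, and the highest of the others was 9, so chance was not excluded for the number of lists.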

How the results depend on the processing

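Xist signal as a covariate, the omission of knockouts 3 and 4 together and the filter at the level of absent transcripts were chosen after seeing the data. Atg12 kept its direction under all 22 alternatives (log2 difference -0.98 to -0.88, adjusted p 0.00408 to 0.499) and passed the threshold in 9 of them. Alternatives that change only the test or the set of genes, or repeat the same values, could not alter this direction. The count of changed genes and of genes lower was 0 with the replicate number as a block (Atg12 -0.93, adjusted p 0.227), with arrays centred on their median (-0.94, 0.068), with Y-linked signal as a covariate (-0.94, 0.112), with Xist signal as a covariate (-0.97, 0.162) and without knockouts 3 and 4 (-0.88, 0.499). Leaving out single arrays gave 0 to 3 changed genes, 0 to 2 higher and 0 to 1 lower, with Atg12 at -0.98 to -0.88 and never past the threshold; without control 4 the 3 genes were Cybb, Oas1g and Hspa1a. Control 4 was the only control with Xist signal. Fits with fewer arrays or more terms have fewer residual degrees of freedom. Otherwise the cause was not tested. An adjusted p under 0.1 or a fold of at least 1.5 gave the same count, 1.

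Lists called numbered 3 to 7 with single arrays left out (higher 1 to 2, lower 2 to 6; Flt3 ranged from -0.27 to 0.0053 there), and the highest came without control 1. They numbered 7 with Xist as a covariate, 6 of them lower. The lists higher numbered 2 under limma-trend. Without knockouts 3 and 4, 1 list was called lower, and the mast cell and basophil list was at -0.28 (adjusted p 0.0505). With an estimated correlation, fry and the exact test, 0 lists were called, higher or lower: adjusted p was 0.301, 0.303 and 0.4 for the interferon-stimulated list (0.32), 0.094, 0.0637 and 0.4 for the megakaryocyte and platelet list (-0.25), and 0.115, 0.0637 and 0.4 for the mast cell and basophil list (-0.31). The shifts of these 3 lists kept their sign in all 24 alternatives, over 0.19 to 0.40, -0.36 to -0.20 and -0.50 to -0.27. Some alternatives keep the shift as it is and could not change the sign of any list, called or not. These include the 3 other list tests, the series values, limma-trend and the replicate block. Among the 25 uncalled lists, 45 of 600 alternative values changed sign, in 14 lists, and 12 were called. Those 12 calls came from camera at the preset correlation. Among 76 named genes besides Atg12, 3 values passed the threshold in an alternative. Robust eBayes gave no list values, because camera has no such option. Weak signal limits genes near the level of absent transcripts, 1.64 to 3.20.

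The titles number both groups 1 to 4, and nothing states that a number marks a shared mouse, litter or day. Correlations of deviations between arrays of the same number were -0.10, 0.12, 0.02 and 0.03, and 2 arrays were closest to their own number, so the numbers were not taken to pair the arrays. With the replicate block the count of changed genes moved from 1 to 0, and the same 3 lists were called.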

Other observations

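The tests of the interferon-stimulated list, of Cdo1 and of early myeloid genes in this part were chosen after the results were seen.

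Over the 8 arrays, the myeloperoxidase gene Mpo was at 12.21 ± 0.04, and the granule protease genes Prtn3, Ctsg and Elane were at 11.84 ± 0.06, 11.62 ± 0.06 and 11.32 ± 0.08 (SD), and of the same early myeloid list Cebpa was at 7.51, Csf1r at 7.07 and Gfi1 at 5.75. Stem cell genes read Mecom 2.95 ± 0.25, Procr 3.49 ± 0.32, Fgd5 3.32 ± 0.20, Slamf1 2.72 ± 0.22 and Ly6a 4.33 ± 0.47, with Txnip at 7.53 and Kit at 8.50, and Cd48, whose product the sort excludes, was at 8.59 in knockouts and 8.63 in controls. These genes were picked after their values were seen, and levels of different probe sets are not on a common scale. Slamf1, whose product the sort selects for, and the mean of Mecom lie within the 1.64 to 3.20 read by transcripts that should be absent. The early myeloid list mean lay above the upper quartile of all signals (5.88 to 6.06) on every array. A weak response of the stem cell probe sets could bear on the low stem cell readings. It would not bear on the high early myeloid readings or on Cd48. How strongly those probe sets respond was not tested, so probe response stays open for the pattern. What share of the samples granulocyte-macrophage progenitors make up cannot be judged from these levels. Other cells in some of the sorted samples also cannot be told apart, since the early myeloid list mean over 22 genes had a range of 0.17 over the arrays (8.95 to 9.12) and so high a baseline would hide a varying share. No biological explanation was tested.

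The interferon-stimulated list was 0.32 higher in knockout (95% interval 0.05 to 0.59). This interval takes no account of the list's choice from 28 lists. The list of mature granulocyte and macrophage genes differed by -0.068 (interval -0.26 to 0.12), but 13 of its 20 members lay above the level of absent transcripts, members went both ways, and the phagocyte genes Lcn2 and Cybb were at 0.66 and 0.87; mature immune cells among the sorted cells cannot be told apart from the other explanations. Of the 35 divisions of the arrays, 2 shifted the list as far. The real one gave 0.318 and the highest of the others 0.366, so chance was not excluded; that other division follows Xist signal. The sex composition of the arrays may contribute and cannot be told apart from genotype: the difference was 0.19 with Xist as a covariate (interval -0.002 to 0.373) and 0.27 with Y-linked signal (interval -0.002 to 0.547), and 3 or fewer arrays per group carry 1 kind of signal. An effect of genotype, whether loss of Atg12 or presence of Mx1-Cre, also stays open.

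Cdo1 was 2.26 higher in knockout and higher on all 4 knockout arrays than on any control array, without passing the test over all genes (limma adjusted p 0.686). In the RefSeq annotation of assembly GRCm38.p6, Cdo1 and Ap3s1 are the measured genes next to Atg12. A change across the genes around Atg12 is not seen, since 9 of the 10 nearest measured genes other than Cdo1 lay above the level of absent transcripts and the largest difference among these was 0.24 (Mospd4), and Ap3s1 was at -0.05. Cdo1 ranked 19 by p, and a rank that high next to Atg12 would have a chance of 0.00157, though the position was looked up after the rank. The difference did not shrink with sex-linked signal as a covariate. It was 2.42 under Xist (interval 0.46 to 4.38) and 2.37 under Y-linked signal (0.60 to 4.13). Cdo1 was picked for its values on these same arrays, and the intervals are wide. They therefore do not exclude a part for sex composition. Chance was not excluded for Cdo1 either. An effect of the altered Atg12 allele on its neighbour may be a candidate explanation and was not tested.

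Other values stood out without a test of their cause. Other chaperone genes, chosen after their values were seen, differed by -0.20 (Dnajb1) to 0.13 (Hspd1). Between these lay Hspb1 (-0.16), Bag3 (-0.02), Hsp90aa1 (-0.01), Hspe1 (0.01), Hspa8 (0.03) and Hsph1 (0.11). They were not a fixed list, and no test compared them with Hspa1a. Knockout 4 carried Xist at 8.12 together with a Y-linked mean of 5.83, although the design describes individual mice. Knockout 3 lay at -39.5 on the first principal component, which held 29.3% of the variance, while the other arrays lay between -12.2 and 14.8, and its estimated weight was 0.411, where the others had 0.801 to 1.39.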
